A study of Mus musculus with 6 samples.

How the data were processed

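RNA was measured by sequencing in CD4+GFP+ regulatory T (Treg) cells sorted by flow cytometry from the liver and spleen of Foxp3-GFP knock-in mice at 12 days of age. In these mice a green fluorescent protein marks cells that express Foxp3, the transcription factor that defines Treg cells. Total RNA was extracted with TRIZOL and made into Illumina libraries, per the labels' protocols. The series holds 3 liver and 3 spleen libraries, numbered here in accession order, and the labels pair none of them. The labels do not say whether the libraries came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical in part. Sex-linked transcripts differed between the libraries of each tissue.

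The deposited values are raw read counts per gene symbol for each library, with no normalization in the table. Reads were processed with HISAT2 2.1, HTSeq 0.11 and the genome build mm9, per the submitters' processing notes. The gene annotation, strand setting and read filters are not given in the sources used here. No coordinates are printed, because the reference at hand was of a later build; it served for gene symbols and for transcript length and GC content. The table held 23366 gene symbols and 5 HTSeq summary rows that name no gene. The summary rows took between 25.5% and 29.0% of all counts that the table held for a library, which included no unaligned reads. These rows were left out of library sizes and tests. Reads that aligned to more than 1 place were not counted for a gene, so genes with near-identical copies, such as the globins, are uncertain. Without a stated strand setting, overlapping and antisense genes cannot be told apart.

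Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 11716, scaled by TMM and tested with the quasi-likelihood F test for liver minus spleen, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM, the counts of a gene relative to the TMM-scaled total of its library, as mean ± SD over 3 libraries, and log2 fold changes carry the standard error (SE) implied by the F statistic. The biological coefficient of variation was 0.129. The groups, the tests, the gene lists and the rule for named genes were fixed in advance. The rule names Foxp3, Il2ra, Ctla4 and Ikzf2, the 10 largest log2 fold changes in each direction among genes past the threshold with non-overlapping libraries and at least 10 CPM in the higher tissue, and the same among genes with at least 10 CPM in both tissues. It adds the 4 members of each biology list with the smallest p and the 2 most abundant members of each marker list. Other genes named in the text were chosen after their values were seen, and some genes the rule picks are not reported here.

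The 36 fixed lists comprised 22 biology lists and 14 lists of markers of other cell types or RNA quality. Lists with at least 5 tested members, 32 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists. The same lists were tested with an estimated correlation and with fry, which asks whether the members of a list move on balance in 1 direction. Older gene symbols were matched through a RefSeq gene table of GRCm38.p6, which gave the table's symbol Beta-s for the adult beta globin Hbb-bs and Folr4 for Izumo1r.

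The methods were tested on simulated counts with the real library sizes. For liver against spleen, 37 of 67 genes changed 1.5-fold, 55 of 66 changed 2-fold and 63 of 65 changed 4-fold were recovered by edgeR among 11577 genes, and 7 of 162 calls were false. In a simulation of the camera test over 11716 genes, a list of 25 genes raised 1.5-fold was called and 0 of 30 unchanged lists were; the simulated genes varied independently, unlike real genes.

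Depth differed between libraries. The liver libraries held 8437055, 10887092 and 10951720 counts in genes, and the spleen libraries 1199410, 11408960 and 11358446. A floor of 3 counts was 2.58 CPM in spleen 1 and between 0.256 and 0.361 CPM in the other libraries. Intervals and floors cover counting error only. No library pair differed by as little as sampling noise: chi-square per degree of freedom was at least 4.71 for each of the pairs.

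Other settings, chosen before the data were examined, were DESeq2 size factors and upper-quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no filter on low counts, a filter of 5 CPM in at least 3 libraries, a minimum absolute log2 fold change of 1, a robust fit, removal of all marker genes before scaling, and leaving out each library in turn. Thinning all libraries at random to the depth of spleen 1, and a block on the sex-linked transcripts a library held (Xist, Ddx3y or both over 10 CPM), were added after seeing the data.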

Results

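Gene expression was measured by RNA sequencing in CD4+GFP+ Treg cells from the liver (n = 3 libraries) and spleen (n = 3 libraries) of 12-day-old Foxp3-GFP knock-in mice. The study's title concerns the accumulation of Treg cells in the neonatal liver and self-tolerance, and the comparison asks how liver Treg cells differ from those of the spleen at this age. Counts in genes were 8437055, 10887092 and 10951720 in the liver libraries and 1199410, 11408960 and 11358446 in the spleen libraries, so spleen 1 was the shallowest. Pearson's r of log2 CPM across genes, which are not independent replicates, was between 0.978 and 0.983 within liver and 0.985 between spleen 2 and spleen 3. It was 0.943 and 0.942 between spleen 1 and the other 2 spleen libraries, and between 0.911 and 0.959 across tissues. The first principal component held 55.5% of the variance and set spleen 1 apart, at -79.0, from spleen 2 and spleen 3 at -9.53 and -7.72 and the liver libraries between 29.1 and 34.8.

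The liver libraries held more transcript of suppressive, effector and proliferation genes, and the spleen libraries more of several naive-cell, T cell receptor signalling and early growth response genes. Markers of NK and CD8 T cells were also higher in liver, in 7 of 14 cases, and those of erythroid cells, granulocytes, macrophages and B cells higher in spleen, in 13 of 14, 13 of 18, 12 of 13 and 7 of 17. Of 11716 genes tested, 1087 were higher in liver and 808 higher in spleen, 16.2% of those tested by edgeR's quasi-likelihood test. An absolute log2 fold change of at least 1 was met by 428 and 267 of them. The libraries of the tissues did not overlap for 32.9% of tested genes, where chance gives 10%. Without spleen 2 the counts were 722 higher in liver and 486 higher in spleen, and without the shallow library spleen 1 they were 1245 and 989. With upper-quartile scaling the larger count was that of spleen, at 954 higher in liver and 1014 higher in spleen. Camera called 21 of 32 gene lists, 10 toward liver and 11 toward spleen; with an estimated inter-gene correlation only the erythroid marker list was called, and that call was lost when any library was left out (adjusted p = 0.0714 to 0.0987 with an estimated correlation).

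Foxp3, the gene that carries the sorting reporter, was at 1266 ± 58.4 CPM in liver and 1160 ± 57.6 CPM in spleen (SD, n = 3 each), with a log2 fold change of 0.13 ± 0.09 (SE) and an edgeR adjusted p of 0.384. Il2ra, the high-affinity IL-2 receptor chain, was lower in liver, at 408 ± 19.1 against 620 ± 32.5 CPM (log2 fold change -0.60 ± 0.09, edgeR adjusted p = 0.000171). Ctla4, an inhibitory receptor, was higher in liver, at 733 ± 34.0 against 400 ± 86.2 CPM (0.89 ± 0.12, edgeR adjusted p = 5.00e-05). Ikzf2, which encodes Helios, was higher in liver by 0.35 ± 0.10 on the log2 scale (edgeR adjusted p = 0.0241). Of the 15 Treg identity genes tested, 3 were higher in liver, 5 higher in spleen and 7 did not pass; adjusted over the list alone the counts were 4 and 7, and without spleen 2 the number higher in liver was 1. Gpr83 (-0.88 ± 0.12) and Folr4 (-0.71 ± 0.10) were among those higher in spleen. Camera did not call the list as a whole (median log2 fold change -0.09, camera adjusted p = 0.161). Fry called it toward spleen (fry adjusted p = 0.0135).

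Genes of effector Treg cells and of suppression were higher in liver. Gzmb, the protease granzyme B, had the smallest p of the tested genes, at 434 ± 40.2 CPM in liver and 67.6 ± 10.1 CPM in spleen (log2 fold change 2.74 ± 0.12, edgeR adjusted p = 1.72e-10). Il10, an anti-inflammatory cytokine, was at 37.9 ± 8.38 against 6.17 ± 1.05 CPM (2.53 ± 0.23, edgeR adjusted p = 4.96e-07). Fgl2 (2.01 ± 0.12) and the inhibitory receptor Tigit (1.58 ± 0.13) were also higher. In the suppressive function list 11 of 17 tested genes were higher in liver, 0 higher in spleen and 6 did not pass; adjusted over the list alone 12 were higher in liver. Its median was 0.97 (camera adjusted p = 2.24e-09, or adjusted p = 0.0797 with an estimated correlation). Gzma and Prf1 of this list are also among the markers of NK and CD8 T cells. In the effector and activation list 15 of 26 were higher in liver, 2 higher in spleen and 9 did not pass; adjusted over the list alone the counts were 16 and 3, and without liver 2, spleen 2 or spleen 3 the number higher in spleen was 1. Prdm1, which encodes the transcription factor Blimp-1, was at 107 ± 3.02 against 26.9 ± 2.88 CPM, and Klrg1 (1.93 ± 0.13), Glrx (1.70 ± 0.12) and S100a4 (1.83 ± 0.15) were higher with it. The list median was 0.53 (camera adjusted p = 1.12e-08; adjusted p = 0.0916 with an estimated correlation).

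Genes associated with tissue Treg cells were higher in liver in 14 of 20 tested cases, with 0 higher in spleen and 6 not passing; adjusted over the list alone 16 were higher in liver, and at equal depth 8 of 17. Il1rl1, the IL-33 receptor, was at 140 ± 16.8 against 43.6 ± 3.60 CPM, and Itgae, the integrin chain CD103, at 152 ± 15.8 against 64.1 ± 5.64 CPM. Cxcr6 was higher by 2.39 ± 0.25 on the log2 scale. The list median was 0.96 (camera adjusted p = 1.30e-10; adjusted p = 0.0529 with an estimated correlation). Of 16 chemokine receptors tested, 9 were higher in liver, 1 higher in spleen and 6 did not pass, and adjusted over the list alone the counts were 10 and 3. Cxcr3 (1.96 ± 0.15), Ccr2 (1.86 ± 0.16) and Ccr3 (2.23 ± 0.21) were higher in liver, and the list median was 1.02 (camera adjusted p = 7.13e-06; adjusted p = 0.0797 with an estimated correlation). Of 9 chemokines tested, 5 were higher in liver, 0 higher in spleen and 4 did not pass, and 6 were higher adjusted over the list alone; without spleen 2 the count was 3 of 9. Ccl5 was at 93.4 ± 12.1 against 13.7 ± 2.11 CPM; Ccl3, Ccl4 and Cxcl2 were higher from levels under 2 CPM in spleen. The chemokine median was 1.62 (camera adjusted p = 0.000285; adjusted p = 0.0797 with an estimated correlation). Integrin and adhesion genes were higher in liver in 11 of 20 cases, higher in spleen in 3 and not past the test in 6; adjusted over the list alone the counts were 11 and 4, and without liver 1, liver 2 or spleen 3 the number higher in spleen was 1. Itgb1 (0.96 ± 0.10), Epcam (1.46 ± 0.18) and Icam1 (0.98 ± 0.14) were among the former, and the list median was 0.42 (camera adjusted p = 0.00141; adjusted p = 0.105 with an estimated correlation). Markers of NK, innate lymphoid, NKT and CD8 T cells were also higher in liver in 7 of 14 cases. Among them are Ccl5 of the chemokine list, Gzma and Prf1 of the suppressive function list and Tbx21 of the T helper list.

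**Figure D1:**
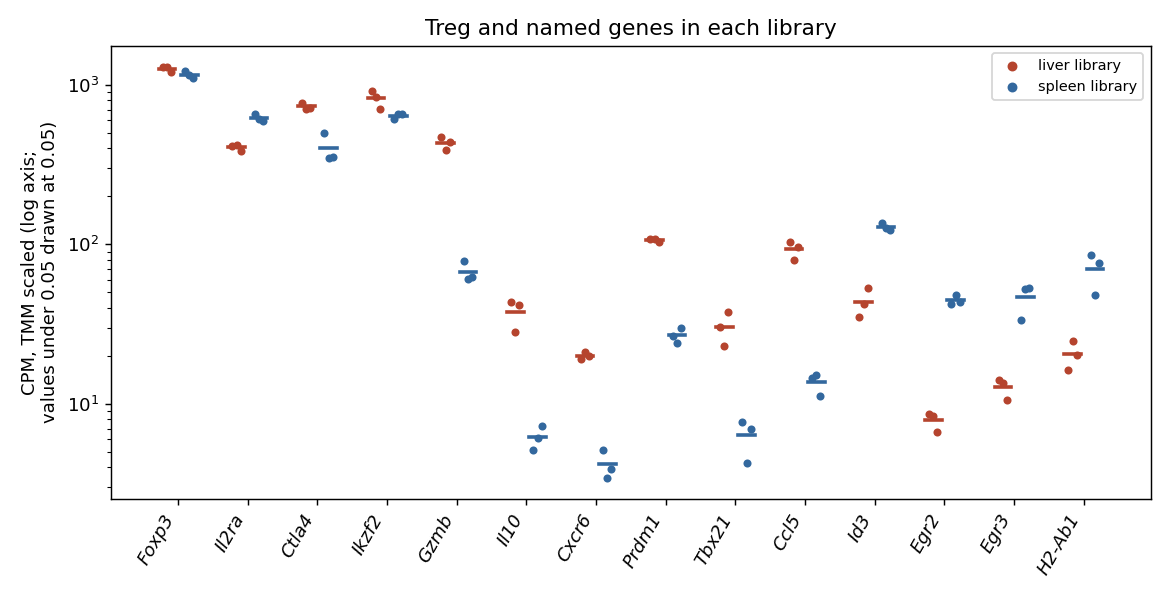
Named genes in each library, in CPM after TMM scaling on a log axis; points are the 3 liver and 3 spleen libraries and bars their means. Gzmb lies at a mean of 434 CPM in liver and 67.6 CPM in spleen, and Foxp3 at 1266 and 1160 CPM.

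Proliferation genes were higher in liver. All 35 tested genes of G2 phase and mitosis were higher in liver, over all genes tested and adjusted over the list alone, with a median log2 fold change of 1.48 (camera adjusted p = 1.07e-35; adjusted p = 0.0797 with an estimated correlation). Mki67, which encodes the proliferation marker Ki-67, was at 888 ± 28.1 CPM in liver and 345 ± 28.1 CPM in spleen (1.37 ± 0.10, edgeR adjusted p = 4.99e-08). Cenpf (1.81 ± 0.12), the spindle motor gene Kif11 (1.59 ± 0.11) and Tpx2 (1.78 ± 0.13) were higher as well. Of 30 S phase genes, 15 were higher in liver, 0 higher in spleen and 15 did not pass; adjusted over the list alone 20 were higher. Without spleen 2 the S phase count was 8, and with all libraries thinned to equal depth 5 of 29. Rrm2, a subunit of ribonucleotide reductase, was at 124 ± 12.0 against 68.7 ± 14.8 CPM, and Uhrf1 (0.60 ± 0.12), Rrm1 (0.55 ± 0.11) and Mcm6 (0.44 ± 0.10) were higher by less. The S phase median was 0.44 (camera adjusted p = 1.44e-06; adjusted p = 0.176 with an estimated correlation).

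Glycolytic and hypoxia-responsive genes were higher in liver in 15 of 22 cases, higher in spleen in 1 and not past the test in 6. Adjusted over the list alone the counts were 18 and 1, and with a library left out the number higher in spleen was 0 to 1. The glycolytic enzyme gene Tpi1 was at 323 ± 16.2 against 123 ± 11.1 CPM (1.40 ± 0.10), and Pgk1 (0.89 ± 0.09), Aldoa (0.96 ± 0.10) and Egln3 (1.98 ± 0.21) were higher. The list median was 0.59 (camera adjusted p = 5.18e-12; adjusted p = 0.0797 with an estimated correlation). Cholesterol and fatty acid synthesis genes were lower in liver in 5 of 22 cases, with 0 higher and 17 not passing, and adjusted over the list alone 7 were lower; the count was 2 without liver 1 or liver 2 and 1 without spleen 2. Scd1 (-1.73 ± 0.26) and Dhcr7 (-0.48 ± 0.14) were lower; the median was -0.16 (camera adjusted p = 0.00534; adjusted p = 0.0916 with an estimated correlation). Of 85 oxidative phosphorylation genes 1 was higher in liver, Sdhd (0.47 ± 0.12), and 84 did not pass; without spleen 2 the count was 0 and without spleen 1 it was 3 of 86. Adjusted over the list alone 0 passed, and the list was not called (median 0.12, camera adjusted p = 0.161). Of 77 cytosolic ribosomal protein genes 1 was lower in liver, Rpl31 (-0.32 ± 0.10), and 76 did not pass, with 0 passing adjusted over the list alone and 0 with each library but spleen 3 left out in turn. That list had a median of -0.16 and was called toward spleen (camera adjusted p = 0.000103, or adjusted p = 0.620 with an estimated correlation). Fry did not call the ribosomal list (fry adjusted p = 0.447). Without the shallow library spleen 1 the ribosomal median was 0.00318 and its camera adjusted p 0.623, and the oxidative phosphorylation list was called toward liver (camera adjusted p = 0.00264), as it was without liver 1 (camera adjusted p = 0.0302) or liver 2 (camera adjusted p = 0.0147). None of these calls held with an estimated correlation (adjusted p = 0.631, 0.648 and 0.598 with an estimated correlation), and without liver 3 the test pointed to spleen (camera adjusted p = 0.863) with a median of 0.02.

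Genes of naive and recirculating T cells were lower in liver in 8 of 18 cases, higher in 2 and not past the test in 8; adjusted over the list alone the counts were 9 lower and 4 higher. The number higher was 0 without liver 1, 1 without liver 2, spleen 2 or spleen 3, and 4 without spleen 1. Id3, an inhibitor of E proteins, was at 43.5 ± 8.99 CPM in liver against 129 ± 7.22 CPM in spleen, and Bcl2 (-0.91 ± 0.10), the transcription factor gene Tcf7 (-0.57 ± 0.11) and Satb1 (-0.61 ± 0.12) were lower too. The list median was -0.32 (camera adjusted p = 0.00131; adjusted p = 0.266 with an estimated correlation). Of 27 T cell receptor signalling genes, 11 were lower in liver, 1 higher and 15 did not pass; adjusted over the list alone the counts were 12 and 1. Without liver 1, liver 2 or spleen 2 the number lower was 4, and without spleen 1 the median was -0.11. The number higher was 0 to 2 with a library left out. The phosphatase gene Ptpn6 (-0.93 ± 0.10), Tespa1 (-1.20 ± 0.19) and the adaptor gene Lat (-0.50 ± 0.10) were lower, and the median was -0.17 (camera adjusted p = 5.57e-05; adjusted p = 0.245 with an estimated correlation). In the IL-2 and STAT5 list 3 of 16 were higher in liver, 4 lower and 9 did not pass, and adjusted over the list alone the counts were 3 and 5; without liver 1, spleen 2 or spleen 3 the number higher was 1. Pim1 was higher (0.87 ± 0.10) while Myc (-0.99 ± 0.11) and Bcl2 were lower. Camera did not call the list (median -0.08, camera adjusted p = 0.115), while fry called it toward spleen (fry adjusted p = 0.0212).

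Immediate early genes went both ways. Egr1 (-1.27 ± 0.11), Egr2 (-2.51 ± 0.18) and Egr3 (-1.94 ± 0.19), transcription factor genes induced by T cell receptor signals, were lower in liver. Klf6 was higher (1.06 ± 0.12), and Fos (0.09 ± 0.13, edgeR adjusted p = 0.697) and Jun (0.14 ± 0.12, edgeR adjusted p = 0.465) did not pass. Of 29 tested members 9 were higher, 5 lower and 15 did not pass; adjusted over the list alone the counts were 10 and 6 (median 0.10, camera adjusted p = 0.535). In the T helper list 5 of 12 were higher in liver, 2 lower and 5 did not pass, and adjusted over the list alone the counts were 6 and 2; with marker genes of other cell types left out 3 of 9 were higher. Tbx21, which encodes the type 1 helper factor T-bet, was at 30.4 ± 7.20 against 6.35 ± 1.82 CPM, and Ifng at 10.8 ± 2.54 against 2.66 ± 0.812 CPM, while Bcl6 (-1.29 ± 0.15) and Tnf (-1.04 ± 0.19) were lower. That list was not called (median 0.16, camera adjusted p = 0.115), and its median ranged from 0.046 to 0.41 over all settings. Of 29 interferon response genes 4 were higher in liver, 0 lower and 25 did not pass, with the same count of 4 adjusted over the list alone and 2 higher without spleen 2. They included Gbp3 (1.30 ± 0.13), Gbp2 (0.81 ± 0.14) and Igtp (0.47 ± 0.12), and the list was not called (median 0.12, camera adjusted p = 0.191). Over all settings the interferon median ranged from 0.0066 to 0.28. The NF-kB and TNF receptor list had 2 of 23 genes higher, Tnfrsf1b (0.76 ± 0.09) and Tnfaip3 (0.79 ± 0.14), 2 lower, Tnfrsf25 (-0.72 ± 0.13) and Rel (-0.80 ± 0.19), and 19 not passing. Adjusted over the list alone its counts were again 2 and 2 (median 0.02, camera adjusted p = 0.954). Of 16 TGF-beta and retinoic acid response genes 3 were higher, 2 lower and 11 did not pass, with the same counts adjusted over the list alone and 1 lower without liver 2, liver 3, spleen 2 or spleen 3 (median -0.11, camera adjusted p = 0.921). This median ranged from -0.15 to -0.027 over all settings. Itgae and Itgb7 (0.42 ± 0.09) were higher, and Ccr9 (-1.14 ± 0.26) and Tgfbr3 (-0.92 ± 0.28) lower.

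**Figure D2:**
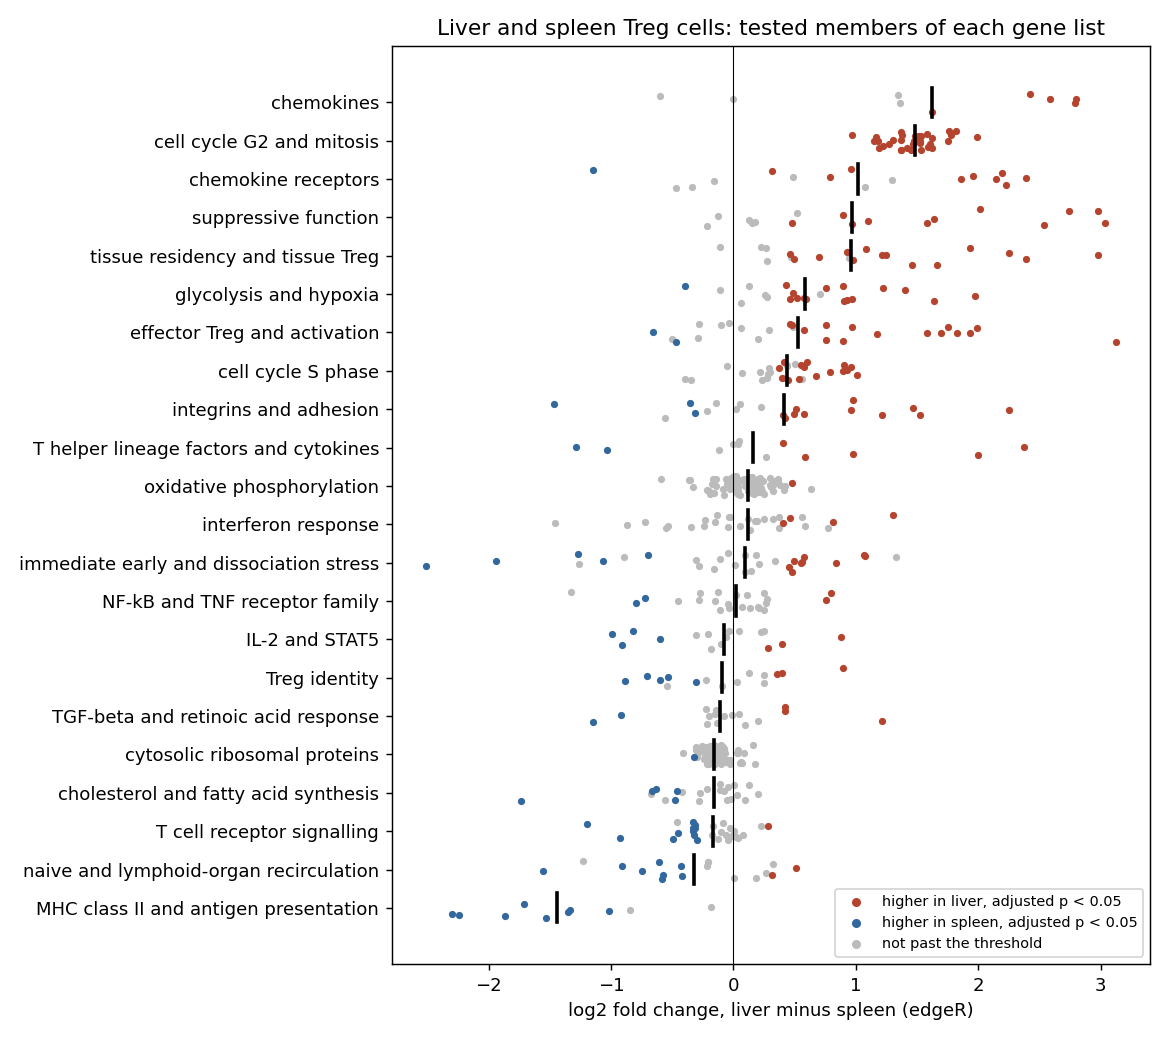
Log2 fold changes, liver minus spleen, of the tested members of the 22 biology lists; each point is a gene, coloured by whether it passed the edgeR test, and black bars are list medians. The median of the 35 G2 and mitosis genes lies at 1.48 and that of the MHC class II list at -1.44.

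Antigen presentation genes of MHC class II were lower in liver in 8 of 10 cases, with 0 higher and 2 not passing; adjusted over the list alone 9 were lower. Cd74, the invariant chain, was at 75.3 ± 7.36 CPM in liver and 191 ± 37.7 CPM in spleen, and H2-Ab1 (-1.71 ± 0.20), H2-Aa (-1.53 ± 0.20) and H2-Eb1 (-1.35 ± 0.21) were lower. The median was -1.44 (camera adjusted p = 4.10e-08; adjusted p = 0.0797 with an estimated correlation). Markers of B cells and macrophages, which express MHC class II, were lower in liver as well. Of 17 B and plasma cell markers 7 were lower, 0 higher and 10 did not pass, with 8 lower adjusted over the list alone and 4 lower without spleen 3, where the median was -0.30 (median of all libraries -0.62, camera adjusted p = 0.000782; adjusted p = 0.245 with an estimated correlation). Cd79a, a B cell receptor subunit, was at 39.0 ± 6.46 against 61.1 ± 12.6 CPM. Of 13 macrophage markers 12 were lower in liver and 1 did not pass, with 12 lower adjusted over the list alone (median -3.41, camera adjusted p = 5.69e-11; adjusted p = 0.0797 with an estimated correlation). C1qc, a complement subunit, was at 0.191 ± 0.255 against 10.5 ± 3.81 CPM and Lyz2 at 59.6 ± 3.79 against 93.9 ± 24.5 CPM.

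Erythroid markers were the most different of the cell type lists. Of 14 tested, 13 were lower in liver and 1 did not pass, with 13 lower adjusted over the list alone (median -5.13, camera adjusted p = 2.10e-16; adjusted p = 0.0259 with an estimated correlation). Slc4a1, the anion exchanger of red cells, was at 50.3 ± 12.7 CPM in spleen, and its 1147 counts there against 2 in liver gave a ratio of 702 (95% counting interval 194 to 5802). Vcam1, found on splenic macrophages, had a spleen to liver ratio of 264 (72.6 to 2184). The globin Beta-s was at 5.97 ± 1.39 against 89.6 ± 35.1 CPM, with near-identical globin copies making its count uncertain. Of 18 granulocyte markers 13 were lower in liver, 1 higher, which was Mmp9, and 4 did not pass; adjusted over the list alone the counts were again 13 and 1. Ngp was at 69.5 ± 5.18 against 174 ± 52.5 CPM and Mpo at 12.5 ± 2.56 against 58.5 ± 6.74 CPM, and the median was -1.11 (camera adjusted p = 1.71e-06; adjusted p = 0.245 with an estimated correlation). With all libraries thinned to equal depth the genes lower in liver were 5 of 5 erythroid, 8 of 11 granulocyte, 3 of 5 macrophage, 2 of 8 B cell and 4 of 7 MHC class II genes.

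NK, innate lymphoid and CD8 T cell markers were higher in liver in 7 of 14 cases, lower in 1 and not past the test in 6; adjusted over the list alone the counts were 8 and 1, and at equal depth 4 of 8 were higher. Nkg7 was at 63.1 ± 13.0 against 23.8 ± 4.82 CPM, and the median was 1.51 (camera adjusted p = 0.000833; adjusted p = 0.121 with an estimated correlation). Of 7 tested hepatocyte markers 4 were higher in liver, 1 lower and 2 did not pass, with the same counts adjusted over the list alone (median 0.70, camera adjusted p = 0.0896). Fry called the list toward liver (fry adjusted p = 0.0133), and 3 of the 7 markers had at most 3 counts in 1 of the tissues. Alb, the albumin gene and among the most abundant transcripts of hepatocytes, was at 5.18 ± 2.66 CPM in liver and had no counts in spleen, where 3 counts over the group are 0.122 CPM. Ass1, whose log2 fold change of 0.70 was the list median, was at 402 ± 26.9 against 249 ± 14.1 CPM. The hepatocyte median was 1.22 without liver 2, 1.88 without spleen 3, 2.66 over 10 genes with DESeq2, 2.57 over 28 without a low-count filter, 0.00445 over 2 at equal depth and -0.15 over 3 with the stricter filter, and the number lower was 0 with each library but spleen 1 left out in turn. Without spleen 1 the hepatocyte list was called toward liver (camera adjusted p = 0.0352), as it was without liver 2 (camera adjusted p = 0.0310) or without a low-count filter (camera adjusted p = 9.29e-05), but not with an estimated correlation (adjusted p = 0.373, 0.231 and 0.111 with an estimated correlation). Of 8 liver sinusoidal endothelium markers 2 were lower in liver, 1 higher and 5 did not pass, with the same counts adjusted over the list alone (median -0.55, camera adjusted p = 0.0347; adjusted p = 0.166 with an estimated correlation). Of 5 stellate cell and fibroblast markers 2 were lower, Ecm1 and Sparc, and 3 did not pass, with 2 lower adjusted over the list alone (median -0.77, camera adjusted p = 0.0271; adjusted p = 0.163 with an estimated correlation). Without spleen 2 the stellate list was not called (camera adjusted p = 0.0645), and without liver 2 its median was -1.36. The endothelium median was -1.12 without liver 1 and -1.01 without liver 2, and the number higher was 0 without liver 3 or spleen 3. Monocyte and dendritic cell markers were higher in 3 of 11 cases, Ccr2 and Irf8 among them, and lower in 1, with 3 and 2 adjusted over the list alone (median 0.33, camera adjusted p = 0.169). With a library left out 1 to 2 were lower, and over all settings the median ranged from -0.087 to 0.56. Conventional CD4 T cell markers were higher in 2 of 9 cases and lower in 2, with 3 and 2 adjusted over the list alone and 1 lower without liver 1, liver 2, spleen 2 or spleen 3 (median -0.18, camera adjusted p = 0.510). The cholangiocyte, megakaryocyte, mast cell and RNA quality lists had 2, 2, 4 and 4 tested members and no list test. Epcam was the 1 gene past the threshold among them, and the nuclear transcript Malat1 was at 1291 ± 231 against 1273 ± 250 CPM.

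**Figure D3:**
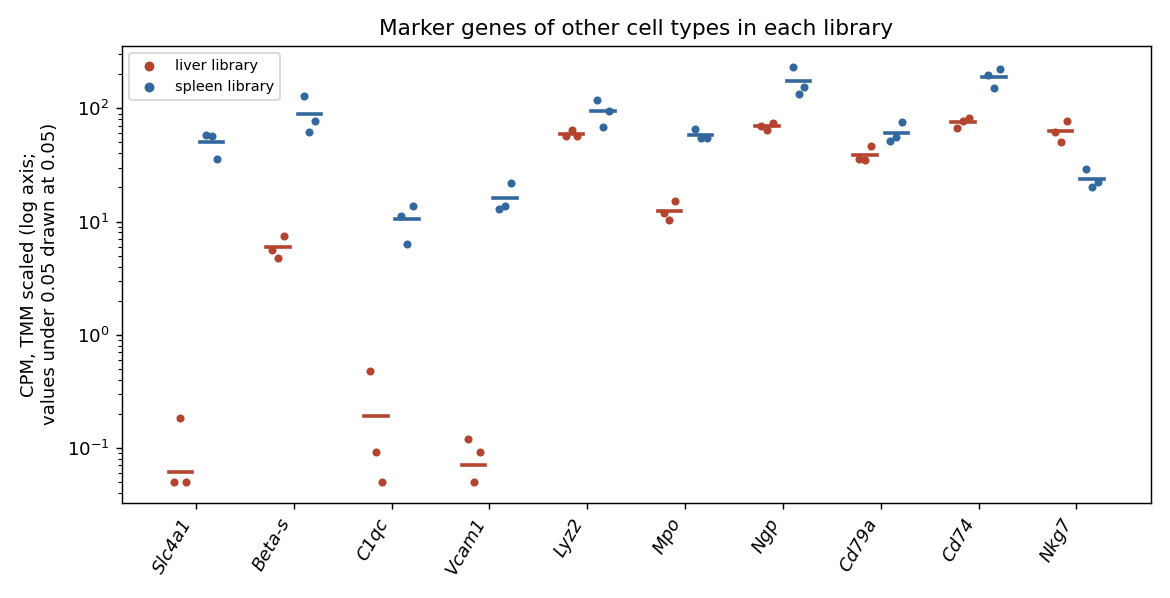
Marker genes of other cell types in each library, in CPM after TMM scaling on a log axis; points are libraries, bars are means, and values under 0.05 are drawn at 0.05. Slc4a1 has a spleen mean of 50.3 CPM, and Nkg7 lies higher in liver, at 63.1 against 23.8 CPM.

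Among the other genes with the largest changes, those higher in liver included Emp1 (2.40 ± 0.33), Tppp3 (2.38 ± 0.40), Sytl3 (2.28 ± 0.31), Frmd5 (2.26 ± 0.15), Hip1 (2.24 ± 0.16), Adam8 (2.24 ± 0.20) and Lgals3, which encodes galectin-3 (2.02 ± 0.15). Gzma, another granzyme, was at 13.3 ± 1.26 against 1.40 ± 0.661 CPM. It is a member of both the suppressive function list and the NK and CD8 T cell marker list. Genes with at least 10 CPM in both tissues that were lower in liver included Lad1 (-2.14 ± 0.16), the cytokine gene Lta (-2.01 ± 0.18), Ryr2 (-1.82 ± 0.13), Hivep3 (-1.71 ± 0.14) and Dtx1 (-1.65 ± 0.12). Aqp1, Tmcc2, Ank1, Abcb4, the erythroid marker Ermap and the endothelial marker Stab2 were each under 1 CPM in liver. In spleen they were between 10.1 and 42.2 CPM on average. RNA of other spleen cells was not tested as a source of Aqp1, Tmcc2, Ank1 or Abcb4.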

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

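Reads that HTSeq placed in no annotated gene lay outside the comparison between the tissues. They made up 16.9% of all counts in the table on average over the 6 libraries, with 16.4% ± 1.67 (SD, n = 3) in liver and 17.3% ± 0.465 in spleen. Their positions were not analysed here.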

How the results depend on the processing

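The labels give no shared replicate number, animal or batch, so no fit paired by labels was made. Equal depth and the block on sex-linked transcripts were chosen after seeing the data. The block, which joins a liver and a spleen library of like Xist and Ddx3y levels, gave 1121 genes higher in liver, 846 higher in spleen and 21 lists, with 1808 of the 1895 main calls shared in direction. As a hint from the data only, the deviations of joined libraries from their tissue means over 5855 other genes correlated at 0.0333, 0.201 and 0.0397, while liver 1 correlated best with spleen 2, at 0.0805, and liver 3 with spleen 1, at 0.0915. Deviations from a shared mean are not independent, and the counting noise of the shallow library spleen 1 enters the spleen mean. These correlations therefore cannot decide whether libraries are paired. Genes higher in liver and in spleen numbered 1087 and 808; leaving out each library in turn gave 722 to 1245 and 486 to 989, with the lowest without spleen 2 and the highest without the shallow library spleen 1. A minimum absolute log2 fold change of 1 left 428 and 267 by its construction. Limma-voom with sample quality weights gave 1243 higher in spleen and 1521 higher in liver; the cause was not tested. Thinning every library to the 1199410 counts of spleen 1 left 9155 genes to test, of which 596 and 419 passed, and 961 of the 1895 genes called at full depth were called in the same direction. Upper-quartile scaling gave 954 and 1014, so the excess toward liver turned. The other settings stayed within 1.5 times of the main counts, and no gene was called in the opposite direction in any setting. Camera called 21 of 32 lists tested; with an estimated inter-gene correlation it called 1, the erythroid list, which was not called with any library left out or with the block (adjusted p = 0.137 with an estimated correlation); fry called 23, of which 20 were shared, and 20 to 23 were called with a library left out. Among lists not called, the immediate early median turned to -0.04 without liver 1, the monocyte and dendritic cell median to -0.09 without spleen 2 and the hepatocyte median to -0.15 with the stricter filter. The NF-kB median, near 0, turned with upper-quartile scaling and without liver 2 or spleen 3, and that of the RNA quality list, of 4 genes and not tested, without liver 1, spleen 2 or spleen 3. Of the 112 named genes past the threshold, 95 stayed past it with the same sign wherever they were tested, apart from the fold minimum. Malat1, not past the threshold, changed sign with upper-quartile scaling (-0.0194) and at equal depth (-0.0309), and without liver 1, liver 2 or spleen 3; it ranged from -0.13 to 0.16 with a library left out, and the cause was not tested. Spleen 1 limits low genes, since 3 counts there are 2.58 CPM.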

Other observations

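The tests of depth, dilution, progenitors, NK or CD8 cells and handling were chosen after the result was seen, as were the 3 lists of the next paragraph.

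Genes of ribosome biogenesis were lower in the liver libraries, and RNA of the erythroid cells, granulocytes and B cells whose markers were higher in spleen was not tested as their source. Of 44 tested, 19 were lower, 0 higher and 25 did not pass, with a median log2 fold change of -0.47. Mdn1 (-1.04 ± 0.10 SE), Nolc1 (-0.77 ± 0.12), Nop56 (-0.58 ± 0.09) and Tsr1 (-0.88 ± 0.16) were among them. As 17 members or their families had been seen before the list was written, only the other 27 were given a list p. Of these 10 were lower, 0 higher and 17 did not pass, with a median of -0.47 (camera unadjusted p = 1.80e-08, and 0.0032 with an estimated correlation). The 27 were picked for the same function as the members already seen and may vary together with them. Their p is therefore no independent test of the pattern. GTPases induced by interferon-gamma were higher in liver in 10 of 15 cases, with 0 lower and a median of 0.57. The list followed a screen of 282 symbol families in which the Gbp family had 7 of 10 members higher (camera adjusted p = 0.00746; adjusted p = 0.992 with an estimated correlation), and 8 of its 10 higher genes had been seen before, so no list p is given. Gbp7 (0.84 ± 0.09) and Iigp1 (1.12 ± 0.33) were among them, and the receptor gene Ifngr1 was at 576 ± 6.66 against 223 ± 6.28 CPM. Genes linked to follicular Treg cells were lower in 8 of 15 cases and higher in 1, with a median of -0.42; 7 of these 9 had been seen before, so no list p is given here either. Btla (-1.04 ± 0.13), Cd200 (-0.82 ± 0.16) and Il21r (-0.42 ± 0.10) were lower beside Bcl6, as were Id3, Tcf7 and Lef1, which the naive list also holds. The gene higher was Sh2d1a (0.47 ± 0.15). Cxcr5 (-0.34 ± 0.15, edgeR adjusted p = 0.139), Tox (-0.12 ± 0.10) and Nfatc1 (-0.13 ± 0.09) did not pass. Nor did Tox2 (0.68 ± 0.25), Pdcd1 (0.29 ± 0.18) and Il1r2 (0.94 ± 0.53). RNA of the B cells whose markers were higher in spleen was not tested as a source of these genes. Eomes, a T-box factor gene, was at 0.825 ± 0.643 CPM in liver and 9.63 ± 0.757 CPM in spleen, opposite to Tbx21.

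Sex-linked transcripts differed between libraries within each tissue. Xist, expressed from the inactive X, was at 1131 CPM in liver 1 and 1258 CPM in spleen 1, where Ddx3y of the Y chromosome had 0 counts. Liver 2 and spleen 2 had Xist at 0.0919 and 0.175 CPM and Ddx3y at 117 and 119 CPM. Liver 3 and spleen 3 held both, with Xist at 455 and 337 CPM and Ddx3y at 52.5 and 79.1 CPM. The labels give no sex. Same-numbered libraries were thus alike in these transcripts in each of the 3 cases, and a fit with this pattern as a block is given with the other settings.

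The erythroid and macrophage markers higher in spleen may come from RNA of such cells in the sorted samples, although the CD4+GFP+ gate would remove them. A second erythroid list, whose members' values had not been seen, had 14 of 18 tested genes lower in liver, with a median of -3.24 (95% interval over genes -5.46 to -1.25), in line with erythroid RNA; 3 of the 18 were also at 10 CPM or more in liver. The matching macrophage test, set in advance, did not come out as macrophage RNA predicts: the median of 17 genes was -0.21 (-2.03 to 0.17), with 7 lower and 2 higher. The interval, added after the median was seen, spans both outcomes, and 8 of the 17 genes are at 10 CPM or more in liver Treg samples. Macrophage RNA therefore stays open. The intervals of both lists take the genes as independent, which genes of 1 cell type may not be, and hold no spread between libraries. Depth argues little, as the first erythroid list had a median of -5.17 without spleen 1, and a true difference between the tissues remains untested.

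The higher G2 and mitosis genes in liver had a median of 1.52 without spleen 1, and 634 genes matched on GC content and transcript length had a median of -0.0021. Dilution of Treg RNA in spleen would raise T cell genes in liver alike, yet the T cell receptor signalling list had a median of -0.17. Cycling erythroid or granulocyte progenitors in liver would bring their own transcripts, and the granulocyte list had a median of -1.11 and the erythroid list -5.13. Markers of NK and CD8 T cells, which the CD4+GFP+ gate would remove, were higher in liver in 7 of 14 cases and lower in 1, Eomes: Prf1 was at 14.3 ± 2.57 against 4.08 ± 1.30 CPM, Klrd1 at 2.94 ± 0.775 against 0.257 ± 0.308, Klrb1c at 3.80 ± 0.342 against 0.970 ± 0.844 and Ncr1, too low to be tested, at 1.42 ± 0.588 against 0.0286 ± 0.0495, while Cd8a at 4.47 ± 0.924 against 3.34 ± 1.33 and Cd8b1 at 7.17 ± 2.05 against 7.66 ± 0.764 did not pass. These levels fix no share of such cells, so cycling NK or CD8 cells stay open, as does an untested difference in Treg cycling between the tissues.

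Egr1, Egr2 and Egr3 were lower in liver with a median log2 fold change of -1.94. A handling response in the spleen cells alone would raise Fos and Jun there as well, but the 4 tested genes among Fos, Fosb, Jun, Junb and Atf3 had a median of 0.18. Of these only Junb passed, and it was higher in liver (0.45 ± 0.10, edgeR adjusted p = 0.0039). Cells of both tissues were sorted, so a response in liver could hide one in spleen, and handling stays open. Without spleen 1 the median of the Egr genes was -2.06. Weaker recent T cell receptor signalling in liver Treg cells is a possible explanation that these data did not test, and RNA of other spleen cells was not tested for these genes.

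The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 1895 genes, and 1 of the 10 splits gave as many; the highest of the others gave 0 by edgeR at the adjusted threshold and 464 at an unadjusted p under 0.05. For lists the real split gave 21 and the highest other 15, with 1 of 10 as large, so camera with its preset correlation called many lists in splits that mix the tissues. Every other split mixed the tissues unequally. It thus kept part of the tissue difference and moved the rest into the spread within groups. The genes and lists of these splits therefore cannot show what edgeR or camera would call without a tissue difference.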
